A study of Danio rerio with 4 samples.

How the data were processed

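Intestines dissected from zebrafish larvae at 6 days post fertilisation were profiled by droplet single-cell RNA sequencing in 4 libraries, per the labels. The first pair of libraries came from an incross of carriers of a whole-gene deletion of meis1b, with 1 library of homozygous mutants and 1 of siblings. The second pair came from the same kind of incross for pbx3a, with 1 library of homozygous mutants and 1 of wild-type siblings. For the meis1b sibling library the sample title reads wild-type plus heterozygous, whereas its genotype field reads wild-type. The title was followed here, and the library is called the sibling library. Per the labels, the meis1b pair was made with 10x 3' chemistry version 4 and the pbx3a pair with version 3.1, so the pairs were processed apart and mutant and sibling were compared only within a pair. With 1 library per group no difference has a replicate check, so no test of genotype was run and no p-value, standard error or count of changed genes is given.

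The deposited values are UMI counts per gene and cell barcode, made by the authors with Cell Ranger 9.0.1 for the meis1b pair and 8.0.0 for the pbx3a pair, per the file headers, and not normalised. Per the submitters' processing notes, Cell Ranger 9.0.1 with STAR 2.5.1b and genome build GRCz11 was used. Those notes do not mention version 8.0.0. The other deposited tables list the gene identifiers with their symbols and the cell barcodes. The barcodes are those called as cells, and the lowest holds 500 UMIs in each library. The gene annotation is not named and no genome sequence was used here, so genes are given by deposited symbol and identifier without coordinates. For 242 symbols that occur more than once the identifiers were kept apart. How reads shared by near-identical genes were counted is not stated, so values of globin and pancreatic enzyme families are uncertain at the level of single genes.

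Barcodes with at least 500 UMIs, at least 250 genes and at most 20% mitochondrially encoded UMIs passed the filter: 9965 of 10503 in the meis1b sibling library, 16294 of 17614 in the meis1b mutant, 8118 of 8452 in the pbx3a wild-type and 8621 of 9492 in the pbx3a mutant. Doublets were called per library with Scrublet in scanpy 1.11.5 (30 components, expected rate 0.06, seed 1). Scrublet called 73 and 341 barcodes in the meis1b sibling and mutant libraries, which were removed. In both libraries of the pbx3a pair it called 0 barcodes, with automatic thresholds of 0.647 and 0.659, so doublets in this pair were in effect not removed. An alternative removed every barcode with a score over 0.25, which were 128, 378, 105 and 171 barcodes in the order above. Kept cells numbered 9892, 15953, 8118 and 8621, with median depths of 2106, 5772, 1213 and 1680 UMIs and median mitochondrial shares of 1.30%, 2.60%, 4.61% and 2.79%.

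The libraries of a pair were clustered together. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen by dispersion within 20 bins of mean expression, without meis1b and pbx3a. The first 30 principal components gave the 15 nearest neighbours of each cell, and the graph weighted by shared neighbours was clustered by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.2. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The meis1b pair gave 51 clusters and the pbx3a pair 47.

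Clusters were named from marker genes of 29 cell classes. A class qualified with a mean log2 ratio of its markers of at least 1 against the mean of the clusters, at least 3 markers at least 2-fold higher in 5% or more of the cells, and at least 2 markers among the 20 leading genes, and the class with most markers there gave the name. A cluster stayed unnamed where another class had more markers among its first 10 genes, or where its median depth was under 1/3 of the library median with no marker in those 10. In the meis1b pair 35 clusters were named to 20 classes and in the pbx3a pair 30 to 13 classes. Classes are resemblances to marker lists and are written with "-like". A cluster counted as epithelial if its class was an intestinal epithelial one, or if it was unnamed and held cdh17, a cadherin gene of intestinal epithelium, at 100 CPM or more. This cdh17 rule was set after the data were seen. It admitted 5 of 16 unnamed clusters in the meis1b pair, with cdh17 at 108.9 CPM or more against 30.9 or less in those left out, and 5 of 17 in the pbx3a pair, with 102.6 or more against 78.0 or less. Unnamed clusters made up 16.6% of epithelial cells in the meis1b sibling library and 23.9% in the mutant, and 26.0% and 26.4% in the pbx3a wild-type and mutant. Unnamed clusters left out of the epithelium held 11.0% and 7.46% of kept cells in the first pair and 24.1% and 34.1% in the second.

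Shares of cells were given with exact Clopper-Pearson intervals, levels as CPM of the summed class counts with exact Poisson intervals, and ratios as log2 of mutant over sibling CPM (pseudocount 0.5 UMI) with exact conditional intervals, all at 95%. Intervals and floors cover counting error only. For a count of 0 the ratio was bounded with a floor of 3 counts over the class and library. Genes were named by a rule based on size. It takes the deleted genes, the TALE homeobox and best4+ marker lists, and in each of the 3 largest named epithelial classes, plus the best4+-like class where it held 20 cells in both libraries, the 5 genes with the highest and the 5 with the lowest ratios. Those needed 50 UMIs in the summed counts and an interval wholly beyond 1.5-fold, and mitochondrially encoded, ribosomal protein and clone-named genes were skipped. The 2 to 4 members of each described list with most UMIs and up to 10 genes past the same bound in the same class and direction in both pairs complete it. Because RNA released from broken cells enters all droplets, the ranking was repeated for genes at 10% or more of their level in the highest class. That screen was added after the data were seen, and genes named through it are called screened.

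Each of 18 gene lists was described by the median log2 ratio of its members and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The gene comparison was tested on simulated data, with Poisson counts drawn around the mean of both libraries and 200 genes changed. The simulated counts held no spread between cells or libraries and no RNA from broken cells. The results below therefore cover counting error only and do not give the share of unchanged genes that passed in the real data. In absorptive-like cells of the meis1b pair (12373 genes) the size rule passed 0% of genes changed 1.3-fold, 62.0% at 2-fold and 100.0% at 4-fold and 8-fold, and 0 of 12175 unchanged genes. For absorptive-like cells of the pbx3a pair (10540 genes) it passed 0%, 50.0%, 100.0% and 100.0% at these folds and 1 of 10341 unchanged genes. For its best4+-like cells (4775 genes) it passed 0%, 38%, 98.0% and 100.0%, and 2 of 4581 unchanged genes. Of 200 simulated unchanged lists, 96.0%, 95.0% and 94.5% in these comparisons fell within the central range of the random lists, and 100.0% of 100 changed lists lay above it.

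The groups, comparisons, cell filter, marker genes, gene lists, naming rule for genes and most alternatives were set before the data were examined. Alternatives of that kind changed the cell filter, doublet removal, clustering resolution, genes used for clustering, joint clustering, depth per cell, denominator, scaling and count minimum. The thresholds for naming clusters, the score limit of 0.25, the marker rule in thinned cells, the exclusion of insulin-rich and lrp2a-rich cells, the compact best4+-like cluster taken alone, the gene comparison in the cluster found without best4+ genes and a list of 41 clock genes were chosen after the data were seen. Scaling each class by the median of its gene ratios moved all log2 ratios by more than 0.1 in 4 comparisons. The median gene ratio was -0.11, -0.23 and -0.16 in absorptive-like, lysosome-rich and ileocyte-like cells of the meis1b pair and -0.16 in absorptive-like cells of the pbx3a pair. No paired analysis was possible because each group has 1 library.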

Results

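The series asks how the transcription factors Meis1b and Pbx3a take part in the development of best4+ cells, a rare intestinal epithelial cell type marked by the ion channel genes best4, otop2 and cftr. Each of 4 groups had 1 library of intestinal cells from 6-day-old larvae. The meis1b sibling library held 45054330 UMIs and the meis1b mutant library 160078023, and the pbx3a wild-type and mutant libraries held 21434404 and 39208112. Epithelial cells numbered 4229 and 6368 in the meis1b sibling and mutant libraries, or 42.8% and 39.9% of kept cells. In the pbx3a pair they numbered 4533 and 3525, or 55.8% and 40.9%. Hepatocyte-like cells made up 11.0% of kept cells in the meis1b sibling library and 35.7% in the mutant, where 1394 of the 5695 formed a cluster of low depth (median 593 UMIs) with 0 sibling cells and with cdh17 at 137 CPM, and exocrine pancreas-like cells 0.591% in the pbx3a wild-type and 5.28% in the mutant. The libraries of a pair thus differed in the share of cells from neighbouring organs, and shares given here are of epithelial cells unless stated.

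The comparison of the meis1b pair asks what the intestine lacks without Meis1b, a TALE homeodomain factor that pairs with Pbx proteins on DNA. In the sibling library meis1b marked mesenchyme, enteric neurons and best4+-like cells. The mutant library was nearly free of meis1b, and with it of best4+-like cells and of their genes best4, cftr and tacr2. Of these genes cftr was also found in another epithelial cluster, of which both libraries held cells. pbx3b was far lower across the mutant epithelium as well, and pbx3a, whose sibling UMIs lay mainly in the missing cells, was lower too, whereas otop2 was still found in enterocytes of the mutant gut. Cells named enteroendocrine-like were scarcer in the mutant library and lysosome-rich enterocyte-like cells more common. Many cells rich in insl5a or adcyap1a UMIs lay outside the enteroendocrine-like class, more so in the mutant library.

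The deleted gene meis1b (LL0000018864) had 2475 UMIs in the sibling library, or 56.0 CPM (53.8 to 58.2), and 47 UMIs in the mutant, or 0.306 CPM (0.225 to 0.407). The log2 ratio was -7.50 (-7.96 to -7.10). Its highest level was in enteric neuron-like cells, with 185 UMIs in 111 sibling cells, or 1648 CPM, against 0 UMIs in 30 mutant cells, at least 19.9-fold lower. In smooth muscle-like cells meis1b was at 309 CPM in the sibling and 1.43 CPM in the mutant library, and in fibroblast-like cells at 238 and 2.11 CPM. For pbx3a (LL0000021344), 202 sibling UMIs over all kept cells stood against 32 in the mutant, with a log2 ratio of -4.44 (-5.04 to -3.91). These levels go with the labels of both libraries.

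Over the epithelium of the meis1b pair the best4+ markers separated into those that were almost missing and those that were not. best4 (LL0000001877) had 186 UMIs in the sibling and 0 in the mutant epithelium, at least 162-fold lower. cftr (LL0000005538), the chloride channel gene mutated in cystic fibrosis, was at 49.3 CPM in the sibling and 0.360 in the mutant epithelium, a log2 ratio of -7.07 (-7.78 to -6.49). An unnamed epithelial cluster of 174 sibling and 205 mutant cells held cftr at 141.3 CPM over both libraries, with best4 at 0.0 and otop2 at 2.3 CPM. The mutant epithelium held too little cftr for its cells of that cluster to reach this level. The neurokinin receptor gene tacr2 (LL0000029907) had 126 sibling and 2 mutant UMIs, a log2 ratio of -7.04 (-10.42 to -5.48). By contrast the proton channel gene otop2 (LL0000021121) stood at 51.9 and 26.1 CPM (-0.99), and within lysosome-rich enterocyte-like cells at 105 and 96.9 CPM (-0.12). The secretin receptor gene sctr (LL0000024326) was at 1.92 and 2.49 CPM (0.36), a difference not detectable over all kept cells (-0.12, -0.47 to 0.27). Sibling best4+-like cells held best4 at 467, otop2 at 1884, cftr at 1809 and tacr2 at 293 CPM.

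**Figure D1:**
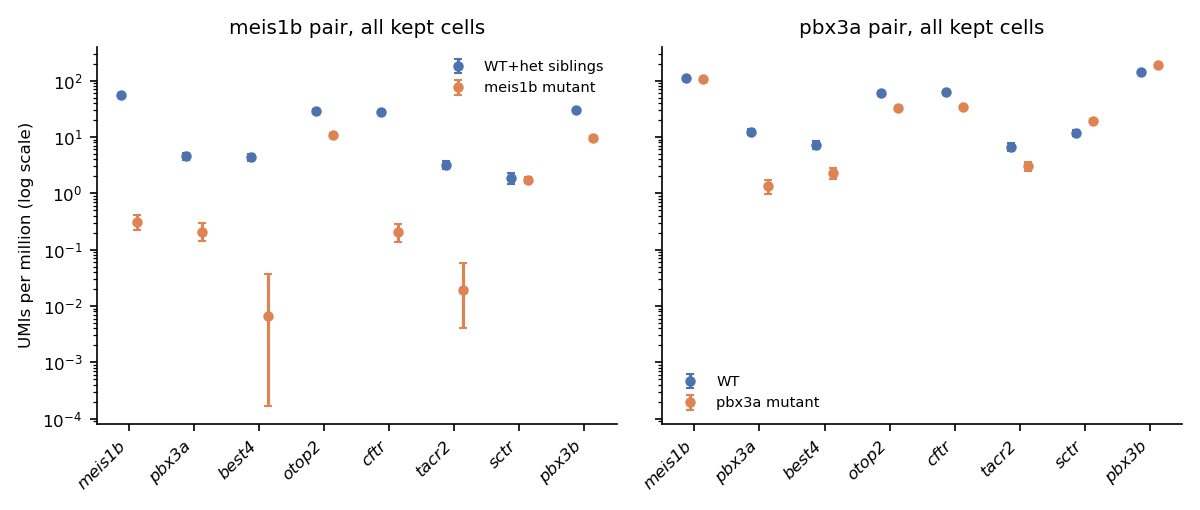
CPM (log axis) of the deleted genes, the best4+ marker genes and pbx3b over all kept cells of each library, with exact Poisson intervals as bars and 1 point per library. cftr stood at 27.4 CPM in the sibling and 0.202 CPM in the mutant library of the meis1b pair, and at 61.5 and 33.9 CPM in the pbx3a pair.

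The best4+-like class held 146 sibling cells, 3.45% of the epithelium (2.92 to 4.05), and 5 mutant cells, 0.0785% (0.0255 to 0.183). These cells were found by a cluster that rests on the marker genes. When the best4+ gene lists were left out of the clustering, no cluster of the meis1b pair was named best4+-like, so no share free of these genes can be given. Counted cell by cell, 264 of 4229 sibling and 12 of 6368 mutant epithelial cells had UMIs of at least 2 of the 5 markers (6.24% and 0.188%), at median depths of 3611 and 7229.5 UMIs. In fibroblast-like cells, which should lack these genes, 2 of 1225 sibling and 0 of 648 mutant cells did, at median depths of 906 and 1379.5 UMIs. With every cell thinned to 1000 UMIs, 107 of 3758 sibling epithelial cells (2.85%) and 2 of 5946 mutant cells (0.0336%) had UMIs of at least 2 markers, with 471 and 422 shallower cells left out. Clustering of the thinned cells gave a best4+-like class of 167 sibling (4.31%) and 124 mutant cells (1.71%), of which 80 and 2 had UMIs of at least 2 markers and which held 51 and 0 best4 UMIs. Of these mutant cells 2 had been best4+-like at full depth, 41 hepatocyte-like and 64 unnamed. A further sibling cluster of 134 cells against 7 mutant cells was absorptive enterocyte-like by its leading genes. It held best4 at 30.9, otop2 at 285 and cftr at 229 CPM in the sibling library, against 0.135, 2.43 and 0.608 CPM in the other absorptive-like cells.

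The TALE family, to which meis and pbx genes belong, was lower as a list in the mutant epithelium (median log2 ratio -0.65, percentile 0.2). The list includes the deleted meis1b. pbx3a was at 8.18 CPM in the sibling and 0.458 in the mutant epithelium (-4.14, -4.79 to -3.58) and its paralogue pbx3b (LL0000021345) at 488 and 67 UMIs (-4.24, -4.64 to -3.88). The sibling best4+-like cells held pbx3a at 442 CPM, and together with the absorptive-like cluster of 134 sibling cells they held 172 of the 192 sibling pbx3a UMIs of the epithelium. Without these cells pbx3a was at 0.924 and 0.361 CPM (-1.36, -2.30 to -0.41, 20 and 22 UMIs), and pbx3b at 22.4 and 1.1 CPM (-4.34, -4.74 to -3.98). Outside the epithelium pbx3b was less different, with a log2 ratio of -0.17 in smooth muscle-like cells and levels of 141 and 78.2 CPM in fibroblast-like cells. meis1a (LL0000018863) was at 33.0 and 13.7 CPM in the epithelium (-1.27), meis2a at 22.3 and 7.34 CPM (-1.60) and pbx1a at 7.54 and 2.85 CPM (-1.41), and meis3 had a log2 ratio of -2.30. Ratios nearer 0 were found for pbx1b (-0.52), pbx2 (-0.65), pknox1.1 (-0.32) and pknox2 (-0.38), and pbx4, pknox1.2 and tgif1 differed by 0.09, 0.05 and 0.09. Over all kept cells, whose make-up differed between the libraries, meis2b had a log2 ratio of -1.90.

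Among the other epithelial classes of the meis1b pair, absorptive enterocyte-like cells made up 51.3% (49.8 to 52.8) of the sibling and 38.3% (37.1 to 39.5) of the mutant epithelium, and lysosome-rich enterocyte-like cells, which take up and degrade luminal protein, 11.7% (10.7 to 12.7) and 24.8% (23.7 to 25.9). Enteroendocrine-like cells made up 6.46% (5.73 to 7.24) and 2.47% (2.1 to 2.88). Shares of ileocyte-like cells (4.73% and 4.52%), goblet-like cells (1.99% and 2.34%) and secretory progenitor-like cells (3.76% and 3.60%) had overlapping intervals. The absorptive-like direction reversed when each library was clustered alone. Of the lysosome-rich class, a cluster of 80 sibling and 216 mutant cells led by galn and adcyap1a also carried the hormone genes insl5a and vipb. Among absorptive-like cells, a cluster led by gsta.1 and dhrs13l1 held 311 sibling and 145 mutant cells. As shares of all kept cells, fibroblast-like cells made up 12.4% and 4.06%, cartilage-like cells 4.63% and 0.476%, smooth muscle-like cells 1.51% and 4.85% and enteric neuron-like cells 1.12% and 0.188%, so the mesenchymal and neural layers also differed between these dissections.

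**Figure D2:**
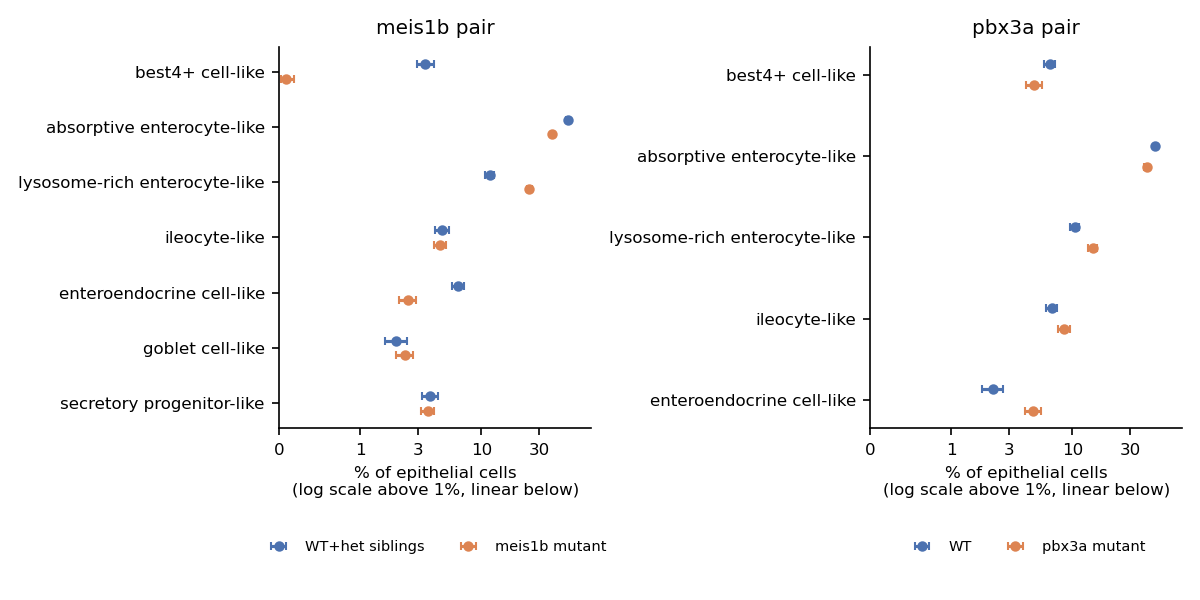
Shares of epithelial cells in each named class, in percent, for the sibling and mutant library of each pair, with exact binomial intervals, on an axis that is logarithmic above 1% and linear below. Best4+-like cells made up 3.45% and 0.0785% of the epithelium in the meis1b pair and 6.49% and 4.82% in the pbx3a pair.

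Within absorptive-like cells the genes with the lowest ratios were best4+ genes and meis1b, whose sibling levels were far higher in the cluster of 134 sibling and 7 mutant cells (meis1b at 62.5 and tacr2 at 31.6 CPM there, against 5.95 and 0.203 in the other absorptive-like cells). best4 had 51 sibling and 0 mutant UMIs, at least 31.1-fold lower, and cftr (-7.24), the secretory phosphoprotein gene scpp8 (-6.08, -9.46 to -4.50, 2 mutant UMIs), tacr2 (-6.03, -11.93 to -4.06, 1 mutant UMI) and meis1b (-5.72) followed. All were below 2% of their level in the highest class. Screened genes at the low end were cbln18, with 369 and 15 UMIs (-5.45), nfil3-6 (-3.38), rorca (-2.95), the p53 target tp53inp1, at 128 and 18.0 CPM (-2.83), and the clock gene npas2, at 53.0 and 7.50 CPM (-2.82). At the high end, the nuclear receptor genes nr1d4b (3 and 893 UMIs, 7.12, 5.79 to 9.62) and nr1d4a (5.33), clock repressors of the REV-ERB family, led, with serpina7 (4.89), apobb.2 (4.17, 2.2 to 10.07, 1 sibling UMI) and vipb (3.69) after them. serpina7 and apobb.2 were at 1.92% and 2.88% of their hepatocyte-like level and vipb at 0.0754% of its enteric neuron-like level. The screen added cenpw (3.52), itln2 (3.42, 2.02 to 5.94, 3 sibling UMIs) and nfil3-2 (3.39). Few cells carried 2 of these: of 2438 mutant cells, 3 held 114 of 130 vipb UMIs and 4 held 46 of 68 itln2 UMIs.

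Lysosome-rich enterocyte-like cells of the meis1b pair shared 1 clock gene with absorptive-like cells at each end. nr1d4b was higher in the mutant library (4.40, 3.06 to 6.90, 3 sibling UMIs) and nfil3-6 lower (-4.02). tagln, ces3 and hpxa had 0 sibling UMIs and were at least 6.21-fold, 5.27-fold and 3.33-fold higher in the mutant, each at 2.09% or less of its level in smooth muscle-like or hepatocyte-like cells, and serpina7 had a ratio of 4.39 (2.48 to 10.29, 1 sibling UMI). Screened genes were grm8a, at 2.26 and 38.7 CPM (3.93), cacng6a (at least 2.30-fold higher), dtwd1 (3.45, 1.53 to 9.35) and exosc6 (3.33, 1.40 to 9.22), the last pair with 1 sibling UMI each. Lower in the mutant were cftr (-5.74), ptgdsb.1 (-3.80) and the globin genes hbbe1.1 (-3.58) and hbbe2 (-3.04), each below 2% of its level in the highest class, and the screened genes gpr137ba (-2.99), slc2a9l2 (-2.96), zbtb16b (-2.85) and ddb2 (-2.76). A single sibling cell held 139 of 151 hbbe1.1 UMIs.

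In ileocyte-like cells, which absorb bile acids, sst1.2 was at least 19.9-fold higher in the mutant library, but 1 of 288 cells held 155 of its 157 UMIs. nr1d4b was at least 6.46-fold higher, and serpina7 (4.24, 2.29 to 10.14, 1 sibling UMI), pcna (3.00, 1.38 to 6.39, 2 sibling UMIs) and rbp2b (2.95) followed. The screen added nr4a1 (2.75), rn7sk (2.49), cdkn1a (2.42) and phlda2, at 140 and 695 CPM (2.31). The lowest ratios belonged to slc24a3 (at least 82.5-fold lower), lrp2a (at least 62.3-fold lower), slc20a1a (-5.48, -8.01 to -4.08, 3 mutant UMIs), slc22a2 (-5.32) and pvalb9 (-3.94). These too lay in few cells: 2 held 87 of 94 sibling slc24a3 UMIs and 3 held 186 of 201 pvalb9 UMIs. Of 200 sibling ileocyte-like cells, 13 had UMIs of at least 2 of lrp2a, slc22a2 and slc20a1a and held 98.6% of the lrp2a UMIs, while 0 of 288 mutant cells did.

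Gene lists over the whole epithelium of the meis1b pair gave these medians, in log2 with the percentile among random lists after each. The best4+ marker list lay at -7.04 (0.0), where tacr2 is the median member and best4 sits below it at its floor. Lysosome and endocytosis genes lay at 1.09 (100.0), with ctsl.1 at 760 and 3669 CPM and lgmn at 127 and 604 CPM, and within lysosome-rich enterocyte-like cells alone the list was at 0.50 (100.0). Cell cycle genes lay at 1.57 (100.0), with pcna at 8.27 and 17.7 CPM and ube2c at 3.37 and 10.6 CPM. Dissociation and stress genes were at 0.68 (100.0), with fosab at 346 and 553 CPM, immune and inflammatory genes at 0.63 (99.97), with irg1l at 4.90 and 22.6 CPM, and regional and HOX/CDX factors at 0.36 (99.96), although cdx1b was at 194 and 94.0 CPM. Enteroendocrine hormones and enzymes lay at -0.78 (0.01), with gcga at 683 and 150 CPM and pyyb at 327 and 110 CPM, secretory fate factors at -0.43 (1.65), although atoh1b was at 29.7 and 49.0 CPM, and lipid absorption genes at -0.64 (0.1), with fabp2 at 8752 and 5762 CPM and apoa4b.1 at 2724 and 1182 CPM. The remaining lists lay inside the central range of random lists. They were the orthologues of human BEST4 cell genes at 0.12 (77.7), Notch pathway at -0.28 (13.4), goblet and mucus at 0.30 (95.6), ion and acid-base transport at 0.11 (85.3), cholesterol synthesis at -0.27 (11.5), protein digestion and brush border at -0.20 (18.4), exocrine pancreas enzymes at -0.03 (58.7) and mitochondrially encoded genes at 0.29 (96.2).

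Members of the human BEST4 list diverged in the meis1b pair. notch2 was at 13.7 and 4.43 CPM in the sibling and mutant epithelium (-1.63), and her9 (LL0000012058), a Hairy-related gene, at 14.9 and 30.8 CPM (1.04). The ratio of ca4b was 0.79 and that of gucy2c 0.59. ca2, outside that list, was at 202 and 79.5 CPM (-1.35) in the epithelium and at 9889 CPM in sibling best4+-like cells. The insulin-induced sterol regulator insig1 was at 202 and 35.4 CPM.

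**Figure D3:**
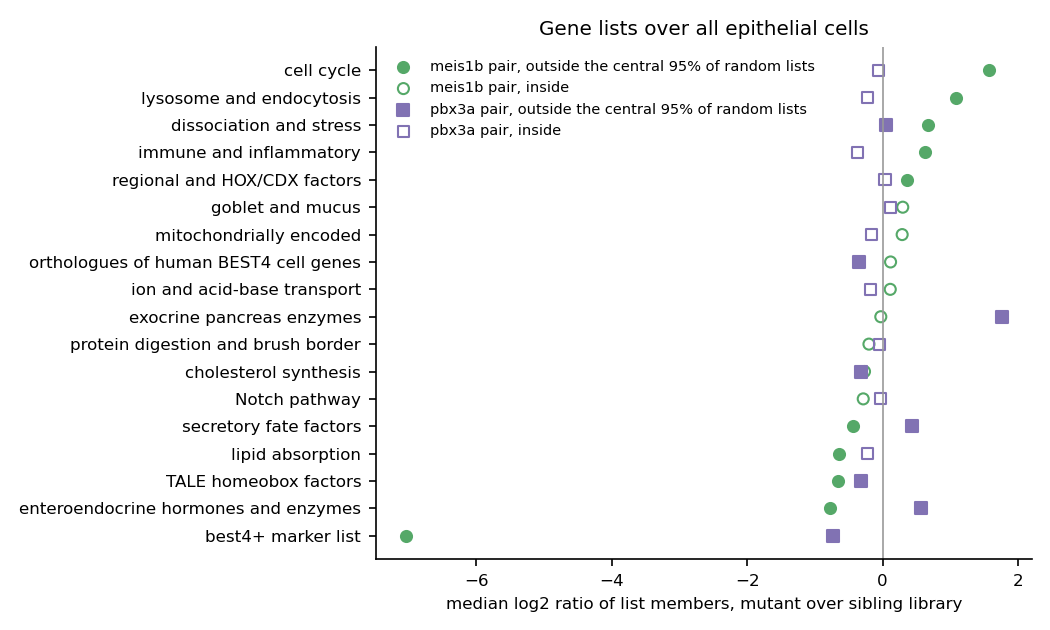
Median log2 ratio of mutant over sibling CPM for each gene list over the epithelium of the meis1b pair (circles) and the pbx3a pair (squares), filled where the median lay outside the central 95% of random lists. Lysosome and endocytosis genes lay at 1.09 in the meis1b pair and -0.22 in the pbx3a pair, and enteroendocrine hormones and enzymes at -0.78 and 0.56.

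The comparison of the pbx3a pair asks what depends on Pbx3a, a partner of Meis factors. Best4+-like cells were present in the pbx3a mutant library, with some of their channel and enzyme genes at lower levels in the cluster found without the best4+ gene lists: otop2, best4 and the carbonic anhydrase gene ca4b stood lowest, and cftr was nearer to the wild-type level. In the class as named from all variable genes the summed markers were not detectably different. A mixed cluster with less best4 made up more of the wild-type than of the mutant cells of that class. The Hairy-related gene her9 and the hormone gene cckb were lower in best4+-like cells of the mutant. meis1b itself stood near the wild-type level. Several hormone genes of enteroendocrine-like cells, such as insl5a and gcga, were more abundant in the mutant epithelium. The hormone genes ghrl and sst2, whose wild-type UMIs lay mostly outside the enteroendocrine-like class, were scarcer.

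The deleted gene pbx3a (LL0000021344) had 256 UMIs in the wild-type library, or 12.2 CPM (10.8 to 13.8), and 50 UMIs in the mutant, or 1.32 CPM (0.983 to 1.75), a log2 ratio of -3.19 (-3.67 to -2.76). In the best4+-like class, where its level was highest, it had 177 wild-type and 32 mutant UMIs (-2.08, -2.69 to -1.55). Of the 50 mutant UMIs 44 lay in epithelial cells. In the compact best4+-like cluster 15 of 90 mutant cells and 62 of 115 wild-type cells had a pbx3a UMI, and outside the epithelium the mutant library had 6 pbx3a beside 6814 pbx3b UMIs. The direction goes with the labels, but the mutant library was not free of pbx3a. meis1b was at 111 and 106 CPM over all kept cells (-0.06, -0.14 to 0.01).

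The naming rule called a pair of clusters best4+-like, of which 1 was mixed. The compact cluster held 115 wild-type and 90 mutant cells, 2.54% and 2.55% of the epithelium, with best4 at 242 CPM. The mixed one held 179 and 80 cells, with best4 at 27 CPM, and beside ca2, cftr and otop2 its leading genes were those of absorptive enterocytes, such as the chitinase genes chia.1 and chia.2 and the amino acid transporter gene slc6a19b. A cluster of this kind was named absorptive enterocyte-like in the meis1b pair. Together they made up 6.49% (5.79 to 7.24) and 4.82% (4.14 to 5.58) of the epithelium. This difference had no stable direction: the mutant share was higher by 0.467 percentage points when the best4+ gene lists were left out of the clustering, and by 0.825 with the stricter cell filter. Cells with UMIs of at least 2 of the 5 markers were 246 of 4533 wild-type (5.43%) and 215 of 3525 mutant epithelial cells (6.10%), at median depths of 1534 and 3138 UMIs. After thinning to 1000 UMIs they were 100 of 2996 (3.34%) and 46 of 2873 (1.60%), with 1537 and 652 shallower cells left out. None of 306 wild-type and 200 mutant fibroblast-like cells (median depths 942.5 and 1361 UMIs) met this rule.

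Over the epithelium best4 was at 9.61 CPM in the wild-type and 3.34 CPM in the mutant library (-1.52, -1.93 to -1.13), otop2 at 77.1 and 47.0 CPM (-0.71), cftr at 79.5 and 48.1 CPM (-0.73) and tacr2 at 8.50 and 4.29 CPM (-0.99), while sctr was at 9.22 and 22.9 CPM (1.31). Among TALE factors, pbx3a had an epithelial ratio of -3.09 (-3.60 to -2.63), meis2a was at 15.3 and 2.98 CPM (-2.35), and meis1a at 26.7 and 8.10 CPM (-1.72), while the ratios of pbx3b (-0.52), meis1b (36.5 and 26.8 CPM, -0.45) and pbx4 (-0.06) were closer to 0. Over all kept cells pbx3b was at 145 and 191 CPM (0.41), and the ratios of meis2b (-0.82), pbx1b (-0.68), pknox2 (0.59), pknox1.1 (-0.40), pbx2 (-0.32), pbx1a (-0.14), pbx4 (-0.18), pknox1.2 (0.13), meis3 (0.10) and tgif1 (0.02) were smaller than that of pbx3a. The make-up of the kept cells differed between these libraries, so these ratios also depend on the share of each tissue.

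To compare gene levels in cells grouped without most of the genes compared, the cluster found without the best4+ gene lists was used, with 123 wild-type and 114 mutant cells. That cluster was still named by its best4+ markers, and ca2, outside those lists, was not withheld from the clustering. otop2 was at 1891 and 791 CPM there (-1.26, -1.49 to -1.03), best4 at 321 and 145 CPM (-1.13, -1.72 to -0.58), ca4b at 1224 and 598 CPM (-1.03, -1.31 to -0.76), ca2 at 11695 and 7989 CPM (-0.55, -0.63 to -0.47) and cftr at 2402 and 1768 CPM (-0.44, -0.62 to -0.27). notch2 had a ratio of -0.36 (-0.68 to -0.03), and the differences in tacr2 (-0.27, -0.82 to 0.28) and sctr (-0.83, -2.26 to 0.49) were not detectable at this depth. her9 was at 181 and 16.9 CPM (-3.30, -5.12 to -2.09) and meis1b at 587 and 730 CPM (0.31, 0.00 to 0.63). The summed UMIs of the 5 markers had a log2 ratio of -0.74 in this cluster, chosen after the data were seen, and of -0.09 (-0.18 to 0.01) in the class as named from all variable genes, the planned comparison. The latter value depends on the make-up of the class, since the mixed cluster made up more of its wild-type cells. In the cluster found without the best4+ gene lists the median of the best4+ marker list was -0.79 (percentile 0.08). That of the orthologues of human BEST4 cell genes was -0.44 (0.58).

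**Figure D4:**
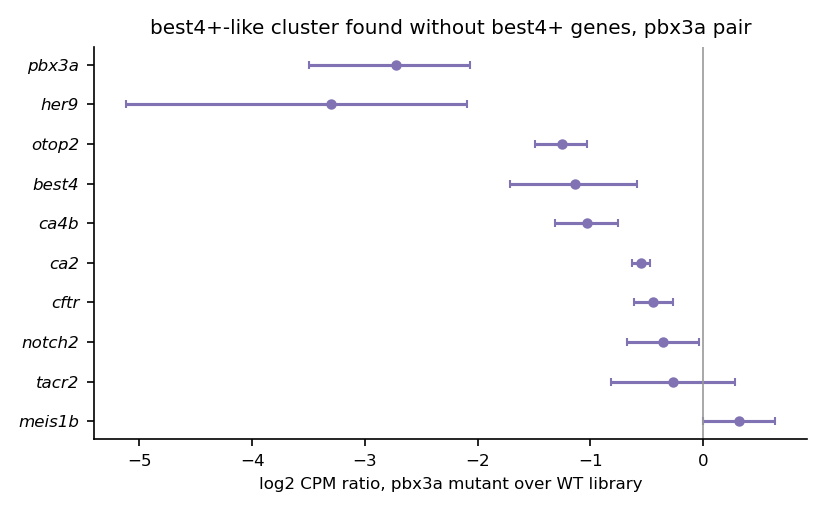
Log2 ratio of pbx3a mutant over wild-type CPM for 10 genes in the best4+-like cluster found without the best4+ gene lists, with exact conditional intervals as bars. otop2 lay at -1.26 and cftr at -0.44, and the interval of tacr2 includes 0.

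In the best4+-like class as named from all variable genes, the lowest ratios in the pbx3a pair belonged to the ghrelin gene ghrl (69 and 0 UMIs, at least 17.9-fold lower), scpp8 (-6.28, -12.18 to -4.36, 1 mutant UMI), the thyroid hormone deiodinase gene dio1, at 117 and 6.99 CPM (-3.98), cckb, at 233 and 37.6 CPM (-2.62), and abcg2b (-2.55). The mixed cluster made up 179 of 294 wild-type but 80 of 170 mutant cells of this class and held all 69 ghrl (57 of them in 4 cells), 165 of 172 dio1 and 67 of 71 abcg2b UMIs of the wild-type, so those ratios depend on the make-up of the class. In the compact cluster alone cckb had 274 and 22 UMIs (-3.69, -4.42 to -3.09) and scpp8 63 and 0, while dio1 (7 and 1) and abcg2b (4 and 5) were too rare to compare. The highest ratios were of pancreas enzymes and other genes of exocrine pancreas-like cells, sycn.2 (6.04, 4.09 to 11.94), c6ast4 (5.24, 3.65 to 8.63), apoda.2 (5.19, 3.82 to 7.71), cpb1 (5.12, 3.52 to 8.51) and prss59.1, at 19.7 and 523 CPM (4.71), all below 1% of their exocrine pancreas-like level. Screened genes there were igsf3 (2.69), dmrt1 (2.06), rgrb (2.06), FADS6 (1.93) and cox6a2 (1.67).

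Absorptive-like cells made up 48.1% (46.7 to 49.6) of the wild-type and 40.9% (39.2 to 42.5) of the pbx3a mutant epithelium, but different clusters held them. A cluster led by apoa1a and osr2 had 72 wild-type and 511 mutant cells, while clusters led by dhrs13l1 (363 and 83), apoea (122 and 26) and mlnl (148 and 0) were mostly wild-type. The class named lysosome-rich enterocyte-like made up 10.4% (9.56 to 11.4) and 14.7% (13.5 to 15.9), but its core cluster, of 357 and 253 cells, made up 7.88% (7.11 to 8.70) and 7.18% (6.35 to 8.08). The higher mutant share of the class rests on a cluster of 61 and 133 cells led by penka and on a mixed one of 55 and 131 cells, whose leading genes held those of lysosome-rich enterocytes beside agr2, atoh1b and muc2.1, which lead the goblet-like cluster of the meis1b pair (mean log2 marker ratios of 2.61 for lysosome-rich and 2.57 for goblet cells). No cluster of this pair was named goblet-like. Ileocyte-like cells made up 6.75% (6.04 to 7.52) and 8.51% (7.61 to 9.48), and enteroendocrine-like cells 2.21% (1.80 to 2.68) and 4.74% (4.06 to 5.49), in a cluster that had a higher mean log2 marker ratio for endocrine pancreas (2.93) than for enteroendocrine cells (2.55). The ileocyte-like direction reversed over all kept cells, and the enteroendocrine-like direction when each library was clustered alone. Of all kept cells, smooth muscle-like cells made up 6.66% and 11.0% and endothelium-like cells 1.88% and 3.87%.

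Among absorptive-like cells of the pbx3a pair, the somatostatin gene sst2 had 542 wild-type and 0 mutant UMIs (at least 256-fold lower), but 14 of 2182 wild-type cells held 515 of them, so this is a difference in a few hormone-rich cells of the class. The hepatocyte genes fetub (-7.50, -13.39 to -5.58, 1 mutant UMI), serpina1 (at least 28.3-fold lower), ttr (at least 24.1-fold lower) and fabp10a (-6.53) were below 0.4% of their hepatocyte-like level. Screened genes were krt96 (-6.07, -9.45 to -4.50, 2 mutant UMIs), ghrl (-5.78), mylpfa (-5.76, -11.66 to -3.80, 1 mutant UMI), the enteropeptidase gene tmprss15, at 21 and 0.346 CPM (-5.76), and actc1b (-4.92, -8.31 to -3.30, 2 mutant UMIs). Higher in the mutant were caspb (4.49, 2.90 to 7.87, 2 wild-type UMIs), apoda.2 (3.85), fbp2 (3.61), gnrh3 (3.49, 2.07 to 6.02, 3 wild-type UMIs), hbbe1.1 (3.16), and by the screen tmtopsa (2.41) and nmur1b (2.07). Few cells also held ghrl (9 cells with 143 of 174 UMIs), mylpfa (1 cell with 33 of 57), actc1b (1 with 35 of 53), fbp2 (6 with 205 of 233) and hbbe1.1 (8 with 197 of 208). Because different clusters made up the absorptive-like class in each library, its ratios may rest on this make-up, which was not tested. Lysosome-rich enterocyte-like cells had apoda.2 (4.14), elovl6 (3.43), stap2a (3.27), pyyb (2.95) and grn2 (2.78) at the high end, with cyp4v7 (2.72) and rgrb (2.60) added by the screen, and apoa2 (-3.83), kcnd3 (-3.23), oaz2a (-3.15), fthl31 (-2.85), dio1 (-2.23), gria3b (-2.22) and il1rapl2 (-1.95) at the low end. The core cluster made up 357 of 473 wild-type and 253 of 517 mutant cells of this class, so its make-up differed. Within the core cluster these ratios kept their direction (apoda.2 at 4.51, apoa2 at -4.35), except that of pyyb, which was lower in the mutant there (41 and 20 UMIs, -1.32, -2.18 to -0.53): 1 mutant cell held 732 of the 779 pyyb UMIs of the class. In ileocyte-like cells lyz had 0 and 363 UMIs (at least 51.4-fold higher), of which 1 cell held 362, followed by c6ast4 (3.68, 2.09 to 7.07, 2 wild-type UMIs), rgrb (2.90), cpa5 (2.73) and txk (2.64, 1.22 to 5.18, 3 wild-type UMIs), with cyp2j20 (1.96) and nmur1b (1.96) added by the screen. ghrl had 161 and 0 UMIs (at least 126-fold lower), 146 of them in 7 of 306 cells, and slc22a2 (-6.62, -12.52 to -4.66, 1 mutant UMI), lrp2a (-5.47), agxtb (-5.12) and oaz2a (-5.05) followed.

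Lists over the epithelium of the pbx3a pair are given in the same way. Lower were the best4+ marker list at -0.73 (0.1), the orthologues of human BEST4 cell genes at -0.35 (1.02), TALE homeobox factors at -0.32 (1.99) and cholesterol synthesis at -0.32 (0.77), with dhcr7 at 155 and 115 CPM and insig1 at 116 and 63.2 CPM. The TALE list includes the deleted pbx3a, and its median without that gene was not computed. Higher were secretory fate factors at 0.43 (100.0), with atoh1b at 15.5 and 32.1 CPM, enteroendocrine hormones and enzymes at 0.56 (100.0), with insl5a at 267 and 643 CPM, gcga at 22.1 and 208 CPM and pyyb at 425 and 611 CPM, exocrine pancreas enzymes at 1.77 (100.0), with prss1 at 338 and 778 CPM, and dissociation and stress genes at 0.05 (98.2), a direction that reversed with the stricter cell filter. Inside the central range were lipid absorption at -0.22 (3.83), lysosome and endocytosis at -0.22 (3.31), immune and inflammatory genes at -0.37 (3.73), ion and acid-base transport at -0.18 (10.4), the Notch pathway at -0.03 (72.8), goblet and mucus at 0.12 (96.8), regional and HOX/CDX factors at 0.04 (95.7), cell cycle at -0.06 (63.0), protein digestion and brush border at -0.04 (69.8) and mitochondrially encoded genes at -0.16 (17.5). Within classes, lysosome and endocytosis genes were lower in absorptive-like (-0.53, percentile 0.03) and ileocyte-like cells (-0.55, 0.0), and lipid absorption genes in lysosome-rich enterocyte-like cells (-0.55, 0.0), where fabp2 was at 1226 and 532 CPM. In the core lysosome-rich cluster alone this last list was at -0.24, inside the central range (percentile 13.3), and fabp2 at 1721 and 876 CPM.

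Of the entries that passed the same bound in the same class and direction in both pairs, the 10 with the largest ratios are given here as the log2 ratio in the meis1b and then in the pbx3a pair, ranked by the smaller of both. In ileocyte-like cells they were lrp2a (-8.56 and -5.47), slc22a2 (-5.32 and -6.62), pvalb9 (-3.94 and -4.80), slc20a1a (-5.48 and -3.45), cyp2k6 (-2.47 and -2.84) and hsd11b2 (-2.21 and -2.02). The lrp2a ratio of the meis1b pair rests on 0 mutant UMIs (at least 62.3-fold lower). In the pbx3a wild-type library 8 of 306 ileocyte-like cells had UMIs of at least 2 of lrp2a, slc22a2 and slc20a1a and held 98.8% of the lrp2a UMIs, with fabp6 at 127 CPM against 33246 in the other ileocyte-like cells. For pvalb9, 3 of those 306 cells held 100 of 112 UMIs. In absorptive-like cells the shared genes were sst1.2 (-2.31 and -4.85), cyp2k6 (-2.18 and -2.09) and sash1a (-1.91 and -2.06), all below 10% of their level in the highest class (1 sibling cell of the meis1b pair held 58 of 82 sst1.2 UMIs, and 8 wild-type cells of the pbx3a pair 320 of 357), and in lysosome-rich enterocyte-like cells grn2 was higher in both mutants (2.25 and 2.78). The screen added tmprss15 (-1.82 and -5.76) and ddr2l (-1.82 and -1.79) in absorptive-like and slc20a1a (-1.75 and -1.80) in lysosome-rich enterocyte-like cells. In the pbx3a pair different clusters made up the absorptive-like class in each library.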

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

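Clustering each library alone, clustering thinned cells and the summed markers in the named pbx3a class were planned, and the other tests of this part were chosen only after the result was seen.

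The enteroendocrine-like share of the epithelium differed in opposite directions in the 2 pairs. It was lower in the meis1b mutant library, by -3.99 percentage points, and higher in the pbx3a mutant library, by 2.53 percentage points. The difference between the pairs was not tested, since each rests on 1 library per group and the pairs used different chemistries. Hormone genes did not all go with the share: over all kept cells gcga was at 365 and 68.1 CPM in the meis1b sibling and mutant libraries and at 19.3 and 149 CPM in the pbx3a wild-type and mutant, but ghrl was lower in both mutants (181 and 1.48, 23.1 and 1.62 CPM), and so was sst2 (287 and 28.5, 40.3 and 0.980 CPM). These levels also depend on the share of other organs in each library. The class also holds pancreatic endocrine cells. When each library was clustered alone the pbx3a direction was not kept (-0.125). In that pair the class also took in hormone-rich cells unevenly. Of epithelial cells with 5 or more insl5a UMIs it held 37 of 96 in the wild-type and 83 of 138 in the mutant library. For ghrl these were 1 of 25 and 2 of 3, whereas for vipb they were 18 of 33 and 33 of 60. In the meis1b pair the class held 40 of 90 sibling and 18 of 89 mutant epithelial cells with 5 or more insl5a UMIs. For adcyap1a these were 41 of 102 and 32 of 230, whereas for gcgb they were 24 of 25 and 13 of 13. Whether the difference in share comes from the naming of clusters was not tested in either pair.

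Best4+-like cells were almost missing from the meis1b mutant library. Unequal depth is argued against, since the mutant epithelium was the deeper one (median 7229.5 against 3611 UMIs) yet had 12 cells with UMIs of at least 2 markers, against 264. Thinning to equal depth, which could only lower the mutant count further, left 0.0336% (0.00407 to 0.121) of mutant and 2.85% (2.34 to 3.43) of sibling epithelial cells. When thinned cells were clustered, the class named best4+-like held 124 mutant (1.71%) and 167 sibling cells (4.31%), but it was mixed: 2 of the 124 and 80 of the 167 had UMIs of at least 2 markers, best4 had 0 and 51 UMIs, and 41 and 64 of the mutant cells had been hepatocyte-like and unnamed at full depth. The fall of cftr alone does not measure missing best4+-like cells. An unnamed epithelial cluster of 174 sibling and 205 mutant cells, with best4 at 0.0 CPM, held cftr at 141.3 CPM over both libraries. The mutant epithelium held too little cftr for its cells there to reach this level. Of 29 genes outside the lists that were at least 20-fold higher in sibling best4+-like cells, 26 had a ratio below 0. Their median was -2.26 (-2.74 to -1.39), from ptger4c at -7.36 to mt2 at 0.21, id2a at 0.22 and BX248318.1 at 1.41. They were chosen in the sibling library that also forms the ratio, which favours lower mutant values. Most were also lower in the mutant epithelium than in the other sibling epithelial cells (cfd at 44.3 against 121 CPM, npr1a at 0.998 against 4.67). Only mt2, id2a, BX248318.1, zgc:92140 and znf385a were higher. The fall is thus not particular to the missing cells and does not settle whether only the listed marker genes were off. Cells that had lost the whole set of such genes would look the same as missing cells, so a change of identity stays open. Loss of a gut stretch in dissection cannot be told apart from these values. The lowest ratio of mutant to sibling share among the enterocyte-like classes was 0.746, against 0.0227 for best4+-like cells, but within the absorptive-like class a cluster of 311 sibling and 145 mutant cells was at 0.310, the enteroendocrine-like class was at 0.382 and the lysosome-rich class at 2.12, so the regional make-up of the libraries may differ. That best4+ cells do not form without meis1b stays open beside this.

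Clock genes differed in absorptive-like cells of the meis1b pair. Of 38 clock genes measured in absorptive-like cells, 17 passed the size rule, with nr1d4a, nr1d4b, nfil3-2 and bhlhe41 higher in the mutant and 13 lower, among them per1b (-0.82), per2 (-0.86), cry1ab (-2.25), tefa (-0.71) and rorca (-2.95). These are 44.7% of the clock genes, while random sets of genes at the same levels in the same cells had a median of 18.4% (7.89 to 34.2). The clock list was chosen after the data were seen and holds genes that had led the ranking, such as nr1d4b, nr1d4a, rorca and npas2. This comparison therefore cannot decide against depth. Free hepatocyte RNA is argued against, since the 4 higher genes sat at a median of 443% of their hepatocyte-like level while hepatocyte markers sat at 1.93%. Whether the tissues of the larvae share the difference cannot be told apart from these values. In the pooled cells outside the epithelium 94.1% (16 of 17) had the same direction, bhlhe41 being the exception, but hepatocyte-like cells made up 19.1% of that pool in the sibling and 59.4% in the mutant library. In fibroblast-like cells 75.0% did (9 of 12 with at least 20 UMIs). There npas2 went the other way (2.16, 1.47 to 2.96, against -2.82 in absorptive-like cells), while nr1d4b was higher in both (4.995 and 7.12). A different hour of collection may explain part of this, but the labels give no hour, so it stays open beside an effect of genotype.

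In best4+-like cells of the pbx3a mutant library best4 and otop2 were lower, while in the class as named from all variable genes the summed 5 markers were at -0.09 (-0.18 to 0.01). That value depends on the make-up of the class, since the mixed cluster made up more of its wild-type cells. In the compact cluster alone the summed markers were lower in the mutant. A grouping of cells by best4 and otop2 is argued against, since in the cluster formed without them best4 was at -1.13 (-1.72 to -0.58) and otop2 at -1.26 (-1.49 to -1.03). That cluster was still named by its best4+ markers. Dilution by other cells would lower cftr alike, and cftr was at -0.44 (-0.62 to -0.27), which argues against dilution for otop2, while for best4 the intervals touch. Whether some larvae of the mutant library had an intact pbx3a cannot be told apart from these values: the 15 mutant cells with a pbx3a UMI held otop2 at 3.23 times (2.46 to 4.22) the level of the 99 without one, against 0.890 (0.735 to 1.08) in the wild-type library, but best4 at 1.06 times (0.425 to 2.33). The lower otop2 may therefore belong mostly to mutant cells without a pbx3a UMI, which was not seen for best4. Many wild-type best4+-like cells had no pbx3a UMI either, so a cell without one may still hold pbx3a RNA.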

How the results depend on the processing

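The removal of doublet scores over 0.25, the marker rule in thinned cells, the compact best4+-like cluster alone, the gene comparison in the cluster found without best4+ genes and the removal of insulin-rich or lrp2a-rich cells are tests chosen only after the results were seen. Shares here are mutant minus sibling in percentage points, and the cause of a shift was not tested unless stated.

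The ratios of meis1b (-7.50) and pbx3a (-3.19) in their own pairs stayed within their intervals without the cell filter, with doublets kept and in thinned cells. In the meis1b pair 52 of 68 values of the main results stayed within the interval of the reported one, 15 moved and 1 reversed. The best4+-like share (-3.37) was lower in the mutant under every setting that gave a value, although with each library clustered alone no mutant cluster was named so. It was -2.61 in thinned cells, where the mutant class grew from 5 (0.0785%) to 124 cells (1.71%), of which 2 had UMIs of at least 2 markers. It was -6.05 by the marker rule, and -1.44 over all kept cells, where the denominator is larger by construction. With the best4+ genes left out of clustering no cluster was named best4+-like, so there is no value. Absorptive-like cells (-13.0) reversed to 2.47 when each library was clustered alone, and gave -9.64 without scores over 0.25. Clustering alone also gave 4.05 for ileocyte-like cells (-0.207), 3.87 for secretory progenitor-like cells (-0.164), where no sibling cluster got the name (245 and 0 cells) and the value is no measured difference, and 10.0 for lysosome-rich enterocyte-like cells (13.1). The last gave 10.7 with doublets kept and 10.0 without scores over 0.25, and ileocyte-like cells 1.47 without the cell filter. Over all kept cells absorptive-like cells gave -6.65, lysosome-rich 4.90 and enteroendocrine-like -1.78, again by the larger denominator. The summed UMIs of the 5 best4+ markers over the epithelium had a log2 ratio of -2.0047, which was -2.50 in thinned cells and -2.61 as a mean of per-cell CPM. Goblet-like cells without the filter, at resolution 0.6 and without scores over 0.25, and ileocyte-like cells at resolution 0.6 in both pairs, were unnamed and have no value.

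In the pbx3a pair 33 of 59 such values stayed within the interval, 17 moved and 9 reversed. Keeping doublets could not change a value in this pair, where 0 barcodes had been called, and 7 of the 33 come from that setting. The best4+-like share (-1.66) reversed to 0.825 with the stricter filter, 0.714 at resolution 0.6, 0.467 without best4+ genes in clustering, 1.13 with each library clustered alone, 0.826 without scores over 0.25, 0.672 by the marker rule and 0.0162 for the compact cluster. By the marker rule in thinned cells, with the shallower cells left out, it stayed lower (-1.74). Absorptive-like cells (-7.26) gave -11.8 at resolution 0.6, -17.3 at 2.0, -14.2 clustered alone and -11.3 without scores over 0.25. Lysosome-rich enterocyte-like cells (4.23) gave 1.25 with the stricter filter, 1.23 and 1.69 at resolutions 0.6 and 2.0, 1.96 clustered alone and 0.170 over all kept cells. Enteroendocrine-like cells (2.53) gave 1.33 without the filter, 0.828 and 3.90 at those resolutions, 0.705 over all kept cells and reversed to -0.125 clustered alone. Ileocyte-like cells (1.76) reversed to -0.290 over all kept cells. The summed markers in best4+-like cells (-0.09, -0.18 to 0.01) gave 0.0121 with median-ratio scaling, 0.0234 with the stricter filter, -0.74 in the cluster found without best4+ genes and -0.59 in the compact cluster.

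Of the values for named genes, 172 of 181 in the meis1b pair and 237 of 247 in the pbx3a pair stayed within the interval and none reversed. A changed count minimum could not change a named gene's value, and keeping doublets could change no value in the pbx3a pair. The minima of 20 and 200 UMIs gave 30 and 8 of the 172 values. Both minima and the kept doublets gave 40, 11 and 40 of the 237. Of the values for lists, 685 of 706 and 631 of 692 stayed within the interval, and 94 of the 631 come from keeping doublets. Reversals were the orthologues of human BEST4 cell genes in absorptive-like cells of the meis1b pair in thinned cells (0.42), its lipid absorption list in lysosome-rich cells with doublets kept (0.0325), its lysosome list in ileocyte-like cells with a minimum of 20 UMIs (-0.11), and the stress list over the pbx3a epithelium with the stricter filter (-0.0380). Depth limits the genes that can be named: in best4+-like cells of the pbx3a pair the simulated size rule passed 38% of 2-fold changes.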

Other observations

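No test of this part was planned, and all the tests it names were chosen only after the result was seen.

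In the meis1b pair the cluster of 134 sibling and 7 mutant cells with absorptive genes held meis1b at 62.5 and pbx3a at 41.0 CPM in the sibling library, against 5.95 and 0.338 CPM in the other absorptive-like cells. In the pbx3a pair the second best4+-like cluster likewise carried absorptive genes, with 70 pbx3a UMIs in 179 wild-type and 11 in 80 mutant cells.

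Hormone genes went in both directions, and for some of them few cells hold the UMIs. In the meis1b pair gip had 3869 UMIs over the kept sibling cells, with 5 or more in 8 cells, and 1 in the mutant library, and sst2 had 12671 and 4374, with 5 or more in 17 and 5 cells, while within the enteroendocrine-like class ccka was at 2862 and 9185 CPM, cckb at 700 and 2064 and adcyap1a at 1034 and 2339. In the pbx3a pair gcgb had 30 and 4811 UMIs over the kept cells, with 5 or more in 1 and 12 cells, and ghrl 484 and 61, with 5 or more in 26 and 3 cells. Of these ghrl UMIs only 24 and 31 lay in the enteroendocrine-like class. Within the enteroendocrine-like class of that pair insl5a was at 8504 and 19529 CPM, while pyyb, at 18787 and 18996 CPM, was not detectably different (0.016, -0.03 to 0.06). These UMI numbers are not scaled, and the mutant library was the deeper one in both pairs. Pancreatic endocrine cells are part of this class: 30 of 273 and 12 of 157 cells of the meis1b sibling and mutant libraries and 17 of 100 and 7 of 167 of the pbx3a wild-type and mutant libraries held 5 or more UMIs of the insulin gene ins. Without them the share differed by -3.51 percentage points in the meis1b pair and 2.71 in the pbx3a pair. This does not free the class of pancreatic endocrine cells: cells were removed by ins alone, while 38 sibling and 7 mutant cells of the meis1b class held 5 or more UMIs of the somatostatin gene sst1.2, and the pbx3a cluster had a higher mean log2 marker ratio for endocrine pancreas (2.93) than for enteroendocrine cells (2.55).

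RNA of other organs was present in the intestinal classes examined. Hepatocyte markers made up 0.0407% of UMIs of absorptive-like cells in the meis1b sibling and 0.188% in the mutant library, and 0.191% and 0.485% in fibroblast-like cells. Exocrine pancreas enzymes made up 0.123% of UMIs of fibroblast-like cells in the pbx3a wild-type and 0.948% in the mutant library, and 0.0214% and 0.371% in best4+-like cells. The exocrine pancreas-like share of kept cells was likewise higher in that mutant library.

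The difference in lrp2a, slc22a2 and slc20a1a in ileocyte-like cells rests on few cells: 13 of 200 meis1b sibling and 8 of 306 pbx3a wild-type cells of that class had UMIs of at least 2 of them, and 0 of 288 and 0 of 300 mutant cells did. Leaving those cells out changed the ileocyte-like share to a difference of 0.0871 percentage points in the meis1b pair and 1.93 in the pbx3a pair. In the cells that carried these genes fabp6 was at 37293 CPM in the meis1b sibling library, against 83646 in the other ileocyte-like cells, and at 127 against 33246 CPM in the pbx3a wild-type. What these cells are was not tested.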
